A study of Debaryomyces hansenii with 8 samples.

How the data were processed

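Gene expression of the yeast Debaryomyces hansenii was measured on 8 arrays of 2 colours. Per the labels' protocols, each array received total RNA, extracted with trizol, from a coculture with the yeast Yarrowia lipolytica in one dye and from a pure culture of the same age in the other. Growth time was 12 h on 4 arrays and 27 h on the other 4, and the design text describes the 4 replicates as biological. In replicates 1 and 3 of each time the coculture carried Cy5, and in replicates 2 and 4 it carried Cy3. Groups, replicate numbers, times and dyes were taken from the labels alone. Whether RNA of the yeasts in coculture was separated before labelling is not given in the sources used here.

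Per the file headers, the scanner images were read with Agilent Feature Extraction 9.1.3.1, which wrote the deposited spot intensities (mean and median foreground and local background of each dye), the processed signals after its own background subtraction, detrending and dye normalization, the log10 ratio of Cy5 over Cy3 and the 0 or 1 quality flags. The deposited log10 ratio was only set beside other columns and entered no test. A deposited table of the series holds 1 log2 value per spot and array. Set against the scanner values, this log2 table was not a table of normalized ratios: on every array it followed the lowess curve, with a span of 0.3, of the log2 ratio of median Cy5 over median Cy3 signals on mean brightness, with a largest gap between 0.000548 and 0.00354 over arrays. Its direction is therefore Cy5 over Cy3 and it is not centred, with medians per array of 0.169, -0.523, 1.83 and -1.11 at 12 h and -0.0805, -0.318, -0.540 and -0.573 at 27 h. It has no ratio of its own for a gene. It was used only, as a setting added after the data were seen, to rebuild ratios by subtracting it from the ratio of the median signals.

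The array carries 12863 gene spots for 6249 genes, with 1 probe of 40 to 60 bases per gene. Most genes have 2 spots and 5 genes have 75. Of the 6249 gene names, 6229 matched a locus tag in the RefSeq gene table of assembly ASM644v2, and 20 did not. No matched gene had a symbol other than its locus tag, so genes are named by locus tag, and the 31 gene lists fixed before the data were examined, written by gene name and description, had no member to test and gave no result. The genome build of the array design is not named, so the table served only for names, for the order of genes along the 7 chromosomes and for gene length, and no coordinates are printed. Since 95.3% of the lengths are multiples of 3, they are called coding lengths.

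Background was corrected with normexp and an offset of 50 on mean foreground and median local background, in limma 3.58.1 under R 4.3.3. Ratios were normalized within arrays by loess with a span of 0.3, in which control spots and spots flagged as outliers had weight 0. Ratios were then turned to coculture over monoculture on the log2 scale and averaged over unflagged spots of a gene. A gene was tested when at least 50% of its spots were well above background in at least 1 channel on at least 3 of the 4 arrays of at least 1 time, which left 5082 genes. One limma model over all 8 arrays held a mean for each time and a dye term for each gene. It gave the coculture effect at 12 h, at 27 h and the difference between them, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The change of the monoculture from 12 h to 27 h came from a limma separate-channel model over the 16 channels, after loess and Aquantile, with a dye term and an intraspot correlation of 0.238, for 5077 genes. That comparison is between arrays, and array differences that Aquantile does not remove stay in it. Every adjusted p below is from these limma models. Values after ± are standard deviations over 4 arrays, or standard errors where named so. Where a named gene was not well above background in a channel on every array of a time, the number of arrays that measured it is given beside values that rest on them.

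Simulated arrays were run through the same steps over 5082 genes, with the ratio spread of each real gene, taken as 1 value for both times. In them 100 genes changed by 1 and 100 by 2 on the log2 scale at 12 h, at 27 h and in the course, which gave 200 of each for the difference. Of genes changed by 1 on the log2 scale, 89.0% were found at 12 h, 90.0% at 27 h and 98.0% in the monoculture course, and of those changed by 2, 97.0%, 98.0% and 100%. For the difference between times, 81.5% of the changes of 1 and 94.0% of the changes of 2 were found. Unchanged genes made up 4.62% of the calls at 12 h, 6.47% at 27 h, 3.04% for the difference and 6.16% in the course. Simulated monoculture channels had less spread between arrays than the fitted course model holds, so the course shares are likely too favourable. The real arrays had estimated weights of 0.302 to 0.861 at 12 h and 1.21 to 4.14 at 27 h. The shares therefore hold for equal spread at both times and may not carry over to the data. Planted changes were also few and as often up as down. In the real data 51.4% of tested genes were called at 12 h and 61.8% in the course. How the normalization behaves with many or unbalanced changes was not simulated.

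Named genes follow a rule fixed before the data were examined. Since no gene had a functional name, the rule fell back to locus tags: the 2 largest rises and the 2 largest falls among genes past the threshold in each comparison, for 12 h and 27 h only among genes that went the same way on all 4 arrays. The 5 genes with 75 spots are named because of their spot number, and runs of neighbouring genes were named after their values were seen. Groups of genes by coding length and by rank from a chromosome end were also chosen after the data were seen. They were tested with permutations of genes and with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over each family.

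Coculture channels were well above background for 68.3% to 90.7% of genes and monoculture channels for 57.5% to 81.8%. Of the negative control spots, 1.08% were. Between 9 and 108 gene spots per array were flagged, and none was saturated. The root mean square SD of a gene's 2 spots lay between 0.0622 and 0.123 on the log2 scale. The number of arrays limits the precision. Arrays came from 2 slides, each with its own scan: slide 1 held replicates 1 and 4 of 12 h, and slide 2 held the other 6 arrays.

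The alternatives were no background correction, the processed signals of Feature Extraction, median centring, scaling between arrays, other filters on dim probes, no dye term, array weights, the slide as a block, a replicate block, the arrays of 1 time alone, stricter thresholds, and each array left out in turn. For the monoculture course they were quantile normalization, median centring, no filter, a replicate block, a 2-fold threshold and each array left out. The settings added after seeing the data were rebuilt ratios, a dye term for each time, the 12 h arrays of 1 slide alone and, for the course only, the slide as a block. For runs of neighbours, leaving out genes whose probes share bases was also added then. The planned choice of the brightest probe changes nothing with 1 probe per gene.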

Results

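Transcript abundance was compared between Debaryomyces hansenii grown with Yarrowia lipolytica and D. hansenii grown alone. Per its title, the study asked how the first yeast responds to the second. The data were 8 arrays of 2 colours, 4 from 12 h and 4 from 27 h of growth, each with coculture RNA in one dye and monoculture RNA in the other. Of 6249 genes with a probe, 5082 gave enough signal to be tested. Median Cy3 signals per array lay between 98.3 and 279 scanner units and median Cy5 signals between 81.6 and 350, over background medians of 42.5 to 49.0 and 40.0 to 41.0. Log2 ratios of coculture over monoculture correlated across genes with r between 0.461 and 0.891 among the 12 h arrays and between 0.488 and 0.897 among the 27 h arrays. Between a 12 h and a 27 h array, r lay between -0.00522 and 0.336. Genes are not independent replicates in such correlations. Whether the coculture RNA held RNA of Y. lipolytica is not given in the sources used here, and signal of that yeast on the probes was not tested.

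The first question was how the transcripts of D. hansenii differed with and without the partner at 12 h. The strongest rise was that of DEHA2D01452g on chromosome D, 12.4-fold higher in coculture, with a log2 ratio of 3.64 ± 0.39 (SD, n = 4; limma adjusted p = 6.04e-07). DEHA2G05962g followed at 8.74-fold, 3.13 ± 0.50 (SD, n = 4; limma adjusted p = 0.000204). DEHA2D13728g was 11.7-fold lower in coculture, at -3.55 ± 0.43 (SD, n = 4; limma adjusted p = 4.71e-05), and DEHA2F00836g stood at -3.46 ± 0.29 (SD, n = 4; limma adjusted p = 2.9e-06). Among 5082 genes, 1367 were higher and 1247 lower in coculture past the threshold, and 245 and 334 of these differed at least 2-fold. The balance of directions depended on how the arrays were centred: 1875 genes were higher and 719 lower with median centring, and 1754 and 1075 with the processed signals of Feature Extraction. The median log2 ratio of all tested genes was 0.03 as reported, 0.18 with median centring and 0.18 with the processed signals, so counts of rises and falls are relative to the centring. From the 12 h arrays alone 1735 genes passed, and 1654 with only the 2 arrays of slide 1 at 12 h, against 2617 with only the 2 of slide 2.

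Several of the 12 h changes lay side by side on a chromosome. DEHA2E07546g, DEHA2E07568g and DEHA2E07590g, neighbours on chromosome E, were all lower in coculture, with log2 ratios of -1.18, -2.54 and -2.91 and standard errors of 0.15, 0.08 and 0.09. DEHA2E04510g, DEHA2E04532g and DEHA2E04554g on the same chromosome were also lower, at -2.35, -1.23 and -1.39. On chromosome C, DEHA2C02464g, DEHA2C02486g and DEHA2C02508g were higher, at 2.21, 2.55 and 1.15. These genes were chosen after their values were seen, and each had the same sign on 4 of 4 arrays and in every normalization tried. In all there were 5 runs of at least 3 neighbours that changed at least 2-fold in 1 direction, against a mean of 1.31 in 1000 permutations of the tested genes (permutation p = 0.01, adjusted p = 0.013 over the 4 comparisons). Across all neighbouring pairs the 12 h ratios were not correlated beyond chance (r = 0.0133 over 4218 pairs, permutation p = 0.4).

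Short genes were more often lower in coculture at 12 h, and long genes more often higher. Of the 1694 tested genes with a coding length up to 918 bases, 774 were lower and 180 higher. Of the 1687 genes of 1624 bases or more, 165 were lower and 704 higher. Spearman's rho between coding length and the log2 ratio was 0.437 across 5072 genes, with a permutation p of 1e-05, the smallest that 100000 permutations can give. On single arrays rho lay between 0.323 and 0.494 at 12 h and between -0.0203 and 0.247 at 27 h. The mean over arrays was 0.390 ± 0.073 (SD, n = 4) at 12 h and 0.0912 ± 0.121 (SD, n = 4) at 27 h (exact permutation test, two-sided p = 0.0286, the smallest that 4 arrays per time can give). The median ratio of the shortest genes stayed below 0 in all 6 normalizations, from -0.34 to -0.13. On slide 1 and on slide 2 taken alone, rho at 12 h was 0.399 and 0.450.

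**Figure D1:**
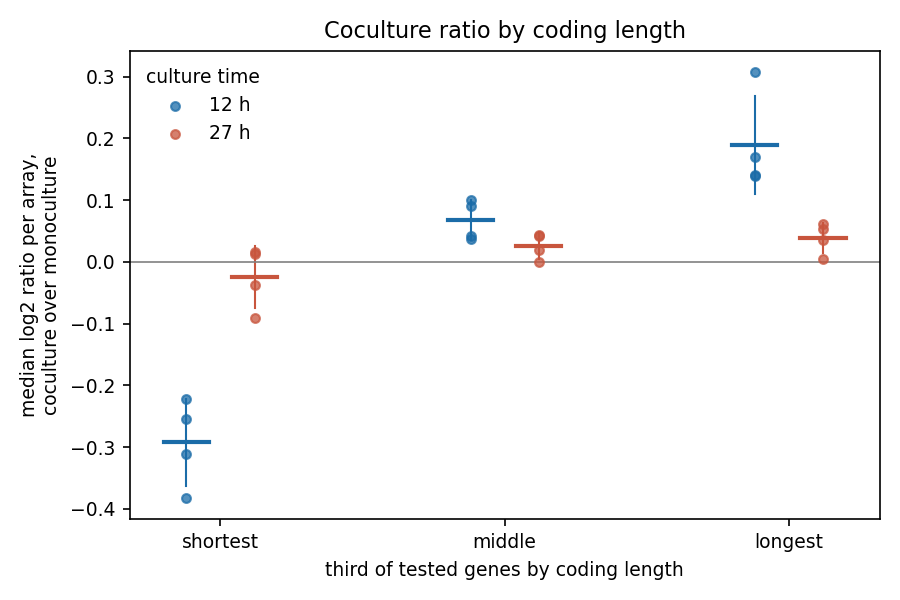
Median log2 ratio of coculture over monoculture on each array (points) for the tested genes split into 3 groups of near equal size by coding length, with the mean and SD over 4 arrays (bars), at 12 h in blue and 27 h in red. At 12 h the medians of the shortest genes lie between -0.38 and -0.22 and those of the longest between 0.14 and 0.31, while the 27 h medians lie between -0.09 and 0.06.

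At 27 h, the same comparison was made in older cultures. DEHA2B15972g on chromosome B was 10.5-fold higher in coculture, with a log2 ratio of 3.39 ± 0.52 (SD, n = 4; limma adjusted p = 5.02e-06), and DEHA2B15928g, which lies on the same chromosome, was 8.14-fold higher, at 3.03 ± 0.67 (SD, n = 4; limma adjusted p = 0.000211). DEHA2D03234g was lower by 2.05 ± 0.69 on the log2 scale, or 4.15-fold (SD, n = 4; limma adjusted p = 0.00249), although its coculture channel was well above background on only 2 of 4 arrays. DEHA2A07920g was 3.85-fold lower, at -1.95 ± 0.42 (SD, n = 4; limma adjusted p = 6.2e-05). In all, 785 genes were higher and 514 lower in coculture, 99 and 46 of them by at least 2-fold. There were 2 runs of 3 neighbours with a rise of at least 2-fold, where permutations gave a mean of 0.032 and at most 1 (permutation p = 0.001, the smallest that 1000 permutations can give, adjusted p = 0.004). One was DEHA2A14344g, DEHA2A14366g and DEHA2A14388g, at 2.06, 2.83 and 1.22. The other was DEHA2C05874g, DEHA2C05896g and DEHA2C05918g, at 1.12, 1.11 and 1.61, in which the probes of the first and second share at least 20 bases with that of another gene, so their ratios may not be separate measurements. Both runs were picked after their values were seen. Without genes whose probes share bases, a test added after the data were seen, 1 run was left, which permutations also reached (permutation p = 0.03, adjusted p = 0.04).

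The 27 h count changed with the settings. It was 2715 when only the 27 h arrays entered the model and 2975 with array weights, 613 with median centring, and 555, 595 and 646 without 27 h replicate 1, 2 or 3. At 27 h the arrays of one dye orientation resembled each other more than the swapped ones did, with r of 0.862 and 0.897 within an orientation and between 0.488 and 0.705 across.

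The coculture effect differed between the times for 2050 genes by the test of the difference itself, 1074 with a higher and 976 with a lower log2 ratio at 27 h. With median centring these were 510 and 1335, and 866 and 1218 with the processed signals. DEHA2E07568g went from 5.80-fold lower in coculture at 12 h, -2.54 ± 0.27 (SD, n = 4), to 2.25-fold higher at 27 h, 1.17 ± 0.15 (SD, n = 4), a difference of 3.70 on the log2 scale (limma adjusted p = 1.45e-05). DEHA2F00836g, the gene lower at 12 h, had a ratio of 0.19 ± 0.32 (SD, n = 4; monoculture well above background on 3 of 4 arrays) at 27 h, a difference of 3.65 (limma adjusted p = 1.45e-05). In the other direction, DEHA2G05962g differed by -3.74 (limma adjusted p = 0.000838), with -0.61 ± 0.85 (SD, n = 4) at 27 h. DEHA2G21032g differed by -3.43 (limma adjusted p = 0.0308), but its 12 h ratios ran from -0.32 to 5.49, and the call was lost in 7 of 23 other settings, with limma adjusted p from 0.000665 to 0.117 over all of them. The 7 were the slide as a block, a threshold of 0.01, and 12 h replicate 3 or any single 27 h replicate left out.

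Across 5082 genes the effects at both times were weakly related (Pearson's r = 0.181, Spearman's rho = 0.180), with no array in common. There were 268 genes higher at both times and 226 lower at both, where independent lists of these sizes would share 211 and 126. Another 244 genes passed the threshold at both times in opposite directions, 107 of them higher at 12 h and 137 lower at 12 h, where independent lists would share 138 and 193. Of 1876 genes called at 12 h and not at 27 h, 1202 passed the test of the difference, and of 561 called only at 27 h, 353 did. For the remaining genes of both classes a difference between times was not shown. These classes rest on 1 spread shared by both times: with the arrays of each time alone the order of the counts turned, with 1735 genes at 12 h and 2715 at 27 h, and with array weights it was 2187 and 2975.

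**Figure D2:**
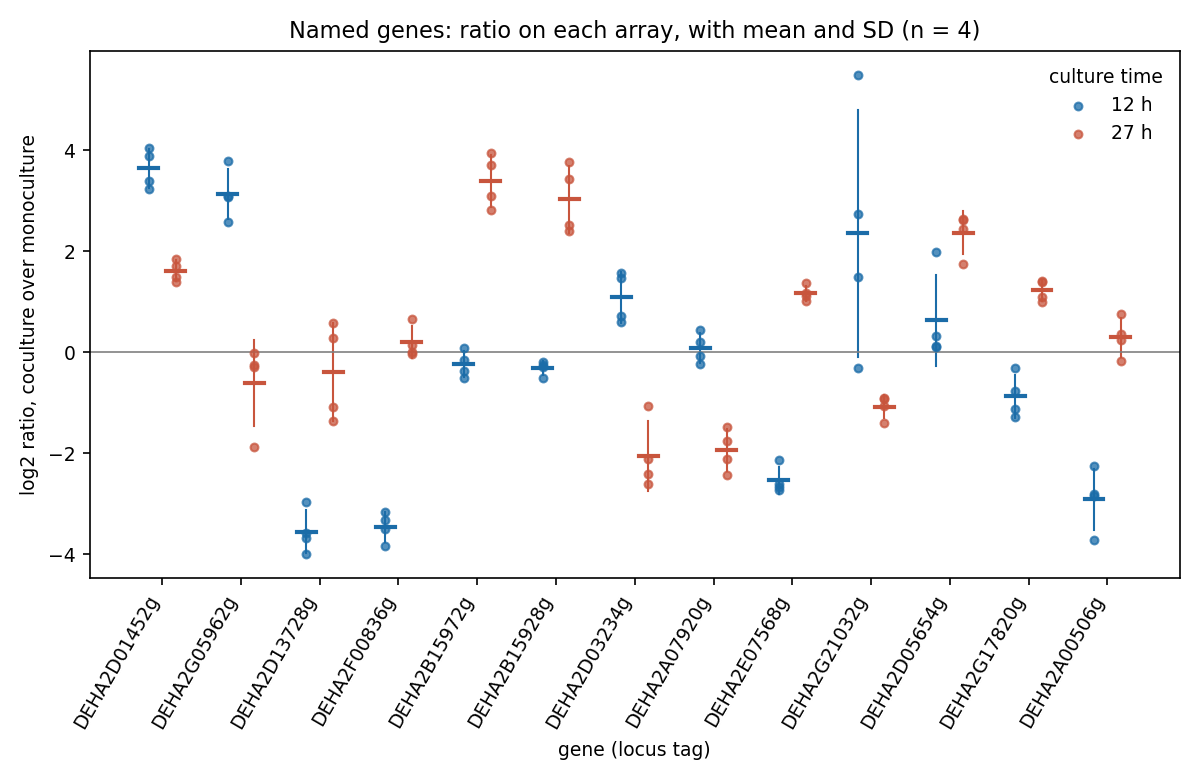
Log2 ratio of coculture over monoculture on each array (points) for the 13 genes named by the rule, with the mean and SD over 4 arrays (bars), at 12 h in blue and at 27 h in red. DEHA2E07568g lies below 0 on all 12 h arrays and above 0 on all 27 h arrays, while DEHA2G21032g is spread from -0.32 to 5.49 at 12 h.

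The change of the monoculture itself from 12 h to 27 h gave the background against which both effects were read. DEHA2D05654g rose by 6.24 on the log2 scale (SE 0.39, n = 4 arrays per time; limma adjusted p = 1.18e-08), from a level of 6.59 at 12 h, where the monoculture was well above background on 1 of 4 arrays, to 12.8 at 27 h. DEHA2G17820g rose 33.2-fold, a log2 change of 5.05 (SE 0.25; limma adjusted p = 1.21e-09). DEHA2A00506g fell 14.1-fold, a log2 change of -3.82 (SE 0.28; limma adjusted p = 4.49e-08), and DEHA2F00836g fell 10.1-fold, a log2 change of -3.33 (SE 0.20; limma adjusted p = 8.5e-09), to a level well above background on 3 of 4 arrays at 27 h. DEHA2D05654g and DEHA2G17820g were also higher in coculture at 27 h, at 2.36 ± 0.42 and 1.22 ± 0.21 (SD, n = 4; limma adjusted p = 0.00128 and 0.00208). DEHA2A00506g was lower in coculture at 12 h, at -2.91 ± 0.60 (SD, n = 4; limma adjusted p = 3.03e-05). In total 1440 genes rose and 1696 fell, 493 and 523 of them at least 2-fold. With median centring within arrays the balance turned, with 1529 rises and 1311 falls. With only the arrays of slide 2, 1524 rose and 1713 fell, and with the slide as a block 1388 and 1629.

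Genes near the ends of chromosomes rose more often in the monoculture course. Within 25 genes of an end, 94 of 156 tested genes rose and 14 fell, against 1341 and 1679 of 4911 elsewhere (odds ratio for a rise 4.03, 95% interval 2.88 to 5.69, Fisher's exact test, adjusted p = 4.37e-16 over 24 tests). Fisher's test takes genes as independent, while neighbouring genes moved together in the course (r = 0.129) and more weakly in the 27 h comparison (r = 0.0655). Its intervals and p-values for these comparisons are therefore likely too narrow and too small. The same held within 10 genes, with 42 of 64 rising, and within 50 genes, with 210 of 430. Few genes near the ends were measurable at all: 45.6% of those within 25 genes of an end were tested, against 83.5% elsewhere. The odds ratio was 2.53 with median centring and 1.38 (95% interval 1.07 to 1.76) when all genes were tested without regard to signal. In coculture against monoculture at 12 h, 15 of the 156 were lower, against 1230 of 4916 elsewhere (adjusted p = 9.05e-06), and 29 were higher, against 1338 (adjusted p = 0.0312). Calls near an end were thus fewer in both directions, with median log2 ratios of 0.058 there and 0.030 elsewhere. These tests therefore do not by themselves show a shift with position, and the part of low signal was not tested. Within 10 genes of an end, 15 of 64 were higher at 12 h, against 1352 of 5008 elsewhere (adjusted p = 0.661), and 4 were lower, against 1241 (adjusted p = 0.000476). Within 50 genes, 96 of 430 were higher, against 1271 of 4642 (adjusted p = 0.0397), and 73 were lower, against 1172 (adjusted p = 0.000281). At 27 h, 36 of the 156 were higher, against 747 of 4916 elsewhere (adjusted p = 0.0191), within 10 genes 11 of 64 were, against 772 of 5008 (adjusted p = 0.77), and within 50 genes 97 of 430 were, against 686 of 4642 (adjusted p = 0.000143).

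**Figure D3:**
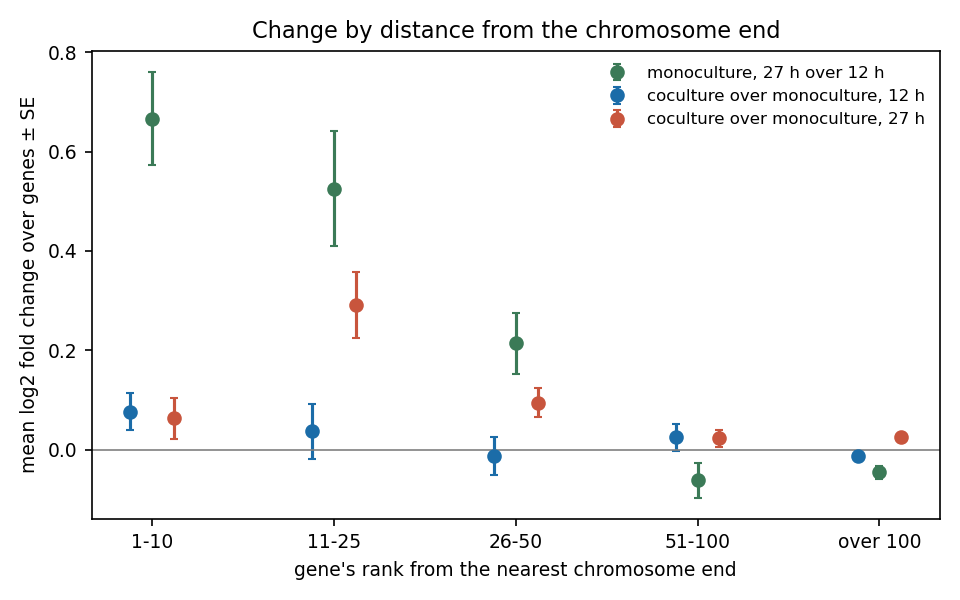
Mean log2 fold change over tested genes, with its standard error over genes, by rank from the nearest chromosome end, for monoculture at 27 h over 12 h (green) and for coculture over monoculture at 12 h (blue) and 27 h (red). In the monoculture course the mean is 0.67 for the 64 genes nearest to an end and -0.05 for genes more than 100 ranks away.

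Neighbouring genes also moved together in the monoculture course. The correlation of log2 changes over 4210 neighbouring pairs was 0.129 (permutation p = 1e-05, the smallest that 100000 permutations can give). There were 15 runs of at least 3 neighbours with a change of at least 2-fold, 7 up and 8 down, against a mean of 6.46 in permutations (permutation p = 0.002, adjusted p = 0.004). Without genes whose probes share bases there were 12, against 5.98 (permutation p = 0.02, adjusted p = 0.04). DEHA2B16192g, DEHA2B16214g, DEHA2B16236g and DEHA2B16258g rose by 1.14, 4.22, 2.86 and 2.90 on the log2 scale, with standard errors of 0.20, 0.50, 0.14 and 0.19. DEHA2F16544g, DEHA2F16566g and DEHA2F16588g changed by -3.13, -2.31 and -1.31. These runs were named after their values were seen.

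Among the 5 genes printed in 75 spots, the ratio of DEHA2D02112g over the 12 h arrays was -0.76 ± 0.92 (SD, n = 4; limma adjusted p = 0.0486), lower on 3 of 4 arrays. That p rests on a model standard error of 0.27, which draws on the arrays of both times. The 27 h ratios of this gene were much tighter, at -0.19 ± 0.05 (SD, n = 4), so the 12 h call is weak. DEHA2D05412g was lower in coculture at both times, at -0.30 ± 0.02 at 12 h and -0.93 ± 0.23 at 27 h (SD, n = 4; limma adjusted p = 0.0163 and 0.000479). DEHA2B01210g, DEHA2F04796g and DEHA2F15202g passed the threshold at neither time, with ratios between -0.18 and 0.04 at 12 h and between -0.63 and -0.27 at 27 h.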

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

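The test of coding length between the times and the test of the control RNA were chosen only after the result was seen.

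The coculture effect at 27 h differed from that at 12 h for 2050 genes. Of all 35 ways to split the 8 arrays into 4 and 4, only the real one, 1 of 35, gave as many calls, and the highest count among the others was 0. The other splits mix 12 h and 27 h arrays, so a difference between the times adds to their residual spread and lowers their counts. A share of 1 of 35 is also the smallest possible, so the splits do not by themselves exclude chance. The same held for the monoculture course, with 3136 calls, 1 of 35 splits and 0 as the highest other count. For 12 h, with 2614 calls, and for 27 h, with 1299, only 1 of the 8 ways to turn the signs of the 4 ratios gave as many, with highest other counts of 0 and 1, but 8 ways are too few for a share under 0.05.

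The 13 genes named by the rule were chosen for a large effect or a large difference, so their passing the limma test of the difference, which 2050 of 5082 genes passed, is no separate evidence. The call for DEHA2G21032g was lost in 7 of 23 other settings. The log2 effect at 27 h minus that at 12 h was 3.70 for DEHA2E07568g, 3.65 for DEHA2F00836g, 3.62 for DEHA2B15972g, 3.34 for DEHA2B15928g, 3.21 for DEHA2A00506g and 3.16 for DEHA2D13728g. It was 2.10 for DEHA2G17820g and 1.74 for DEHA2D05654g. It was below 0 for DEHA2G05962g at -3.74, DEHA2G21032g at -3.43, DEHA2D03234g at -3.14, DEHA2A07920g at -2.03 and DEHA2D01452g at -2.03. At 12 h, DEHA2B15972g was well above background on 2 of 4 arrays in coculture and 1 of 4 in monoculture, DEHA2D03234g on 1 of 4 in monoculture and DEHA2D05654g on 3 of 4 in coculture and 1 of 4 in monoculture. At 27 h, DEHA2D03234g was so on 2 of 4 arrays in coculture and DEHA2F00836g on 3 of 4 in monoculture. The differences of these genes rest partly on signals near background.

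In 6 of the 50 groups of 4 values examined, 1 array stood far from the other 3 by Dixon's test, where chance gives about 1 in 20. At 12 h, replicate 4 had a log2 ratio of 1.98 for DEHA2D05654g, against 0.10 to 0.32 on the others, and 0.61 for DEHA2D02112g, against -1.30 to -1.07. At 27 h, replicate 4 had -1.88 for DEHA2G05962g, against -0.29 to -0.02, -0.27 for DEHA2F15202g, against -0.77 to -0.73, and -0.12 for DEHA2D02112g, against -0.22 to -0.21. Replicate 2 of 27 h had -0.71 for DEHA2F04796g, against -0.16 to -0.09.

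The dependence on coding length differed between the times, with a mean Spearman's rho 0.299 higher at 12 h than at 27 h, and across genes rho was 0.218 in the monoculture course, which shares the 12 h monoculture channels. Signal intensity as the whole source was argued against by rho of at least 0.385 within each of 3 groups of mean signal. Normalization was argued against by rho of at least 0.342 under 5 other settings. RNA integrity that differs between the channels stays open: rho was at least 0.323 on each 12 h array, but no value of the files shows RNA integrity or the place of a probe in its transcript. A change of D. hansenii in coculture that depends on the length of its genes may also be the source, and was not tested.

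The control RNA ratios differed between the dye orientations. The gene ratio minus the control ratio, turned to coculture over monoculture on the log2 scale, had a mean of -1.14 ± 2.43 (SD, n = 4; exact permutation of signs, p = 0.5) at 27 h, with -3.23 on the arrays with coculture in Cy5 and 0.94 on the others. At 12 h it was 0.73 ± 0.85 (SD, n = 4; exact permutation of signs, p = 0.25), with 0.09 and 1.37 in the same order, and 4 arrays cannot give a p below 0.125. No change of total mRNA was therefore read from them.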

How the results depend on the processing

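The rebuilt ratios, a dye term for each time, the arrays of 1 slide alone, the slide as a block in the course, and all tests of coding length and chromosome ends were chosen only after the result was seen. For genes named by the rule, 333 of 340 values in other settings stayed on the same side of the threshold and 0 reversed. The other 7 all concerned DEHA2G21032g. These genes were chosen for large effects, and filters, the dye term and blocks left many of their estimates unchanged, so 0 reversals is no separate support. DEHA2F00836g, DEHA2B15972g and DEHA2D03234g failed the strictest filter and were left out of the count there. Spearman's rho of coding length at 12 h ranged from 0.342 to 0.492, and the odds ratio of rises near chromosome ends, 4.03 as reported, from 1.38 without the filter to 4.38. Counts moved by over 1.5 times as follows. At 27 h, 1299 became 613 with median centring, 2975 with array weights, 837 with a replicate block and 2715 with the arrays of that time alone; the 12 h arrays had weights of 0.302 to 0.861 against 1.21 to 4.14. At 12 h, 2614 became 1735 with the arrays of that time alone and 1654 with those of slide 1, against 2617 with as many arrays of slide 2. A 2-fold threshold left 579 genes at 12 h, 145 at 27 h, 635 for the difference and 1016 in the course, and an adjusted p below 0.01 left 554 at 27 h and 1077 for the difference. Leaving out single arrays gave 2170 to 2690 at 12 h, 555 to 1741 at 27 h, 1441 to 2404 for the difference and 2820 to 3340 in the course; the lowest at 27 h, 555, 595 and 646, were without its replicates 1, 2 and 3. The cause was not tested.

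With the replicate number as a block the counts at 12 h, at 27 h, for the difference and in the course were 2276, 837, 1600 and 3143. The numbers were not taken to pair samples, since nothing in the labels says that a number marks the same culture at both times. Deviations of same-numbered arrays correlated with r between -0.0493 and 0.0657 over 4 pairs, which are too few to decide it. Same-numbered arrays also share the dye orientation. With the slide as a block the counts in the same order were 2524, 1191, 1506 and 3017. The deposited value table as an alternative and the 31 gene lists were not run, since the table holds a trend and no gene had a functional name; the brightest probe changes nothing. For lack of signal over background, 1167 genes were not tested.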

Other observations

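The test with all genes regardless of signal was chosen only after the result was seen, and both patterns weighed here were found and tested on the same data.

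Genes lower in coculture at 12 h were often genes that fell in the monoculture by 27 h. Both lists use the 12 h monoculture channels, so an excess over independent lists is not by itself a shared effect. Of 1245 genes lower at 12 h, 766 fell in the monoculture course, where independent lists would share 416, and 135 rose, where they would share 353. Of 1364 genes higher at 12 h, 492 rose, where independent lists would share 387, and 240 fell, where they would share 456. DEHA2F00836g, at -3.46 at 12 h, and DEHA2A00506g, at -2.91, were among those that fell in the course, and DEHA2D01452g, at 3.64 at 12 h, rose by 3.17. Other named genes went against this: DEHA2G05962g, at 3.13 at 12 h, changed by -0.86 in the course (limma adjusted p = 0.0288), and DEHA2G17820g, at -0.87, by 5.05. DEHA2E07568g, at -2.54 at 12 h, did not pass the threshold in the course, at 0.06.

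Across 5077 genes r between the 12 h effect and the course was 0.396, while simulated unchanged groups gave 0.434 on average, but the covariance was 0.231 against 0.0109 simulated, a difference of 0.220. With the 12 h arrays split so that no channel was shared, r was at least 0.175 over 4 splits. That argues against noise of shared channels as the whole source. Values of at least 0.339 within groups of mean signal and 0.221 within groups of coding length argue against brightness and length alone. With replicate 4 left out r was at least 0.183, which argues against that single array. Both measures still subtract a 12 h monoculture level in every split. Genes whose 12 h monoculture differs from both other cultures therefore give a positive r, and the simulated groups held noise alone. Neither the splits nor the simulation can exclude this. A coculture that is further along the course of the monoculture at 12 h may be a candidate explanation. These values do not set it apart from such a 12 h monoculture, and growth stage was not measured here.

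Genes within 25 ranks of a chromosome end rose more often in the monoculture course, with an odds ratio of 4.03. The lower 95% bound was 3.34 over groups of mean signal, 2.52 without genes whose probes share bases with another, and 2.79 with the arrays of slide 2 alone, which argues against each of these as the whole source. With all genes tested the odds ratio was 1.38 with a lower bound of 1.07, so the filter on dim probes may account for much of the size of the excess of rises. All these bounds take genes as independent, while neighbouring genes moved together in the course (r = 0.129). They are therefore likely too high, and a bound of 1.07 does not exclude an odds ratio of 1. Without the filter, 4.97% of the genes near an end fell, against 30.0% elsewhere. Only 45.6% of the genes near an end had enough signal to pass the filter, against 83.5% elsewhere. A gene at background has no room to fall, so this gap is no separate support for a change at the ends. A change at chromosome ends with culture age stays open as a hypothesis, and nothing in these data tests its mechanism.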
